A study of Mus musculus with 6 samples.

How the data were processed

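The series compares cells sorted as mouse RGCs from Myh9/10-floxed animals after AAV2-GFP (labelled WT, n = 3) or AAV2-Cre (labelled dKO, n = 3), each library made from 3 pooled retinas. Per the labels' protocols, total RNA was extracted from FACS-purified cells and made into libraries with a stranded total RNA kit that does not select for poly(A) tails. The deposited values are raw read counts per Ensembl gene, whole numbers that the authors had not normalized. Per the submitters' processing notes, STAR 2.7.0d, DESeq2 1.22.2 and the GRCm38 build were used; the counting program, its strand setting, its handling of reads with several matches and the annotation release are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

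The table holds 55573 genes, of which 21821 have a count in any library. Positions and biotypes were taken from GENCODE M21 on GRCm38, where 55480 of the IDs were found. Library totals were 4569880 to 6146226, but counts outside the ribosomal RNA row CT010467.1 (chromosome 17, which names a gene and stayed in the table) were only 346037 to 1636581, and this smaller depth sets the precision of every other gene. CPM are counts scaled to a common library size, the ribosomal RNA row included, after scaling by TMM with factors of 0.641 to 3.43, the highest for dKO replicate 3.

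Genes were kept by edgeR's filterByExpr on the group (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3), quasi-likelihood F test, two-sided, with the group as the only term; genes past a Benjamini-Hochberg adjusted p of 0.05 were called. The common biological coefficient of variation was 0.0820. Standard errors are the log2 fold change divided by the square root of F. Before the data were examined, 31 gene lists, the design, the alternatives and a rule for named genes were fixed. The rule names Myh9, Myh10 and Myh14, then, among called genes with a mean of at least 1 CPM and no overlap between groups, the 10 largest changes and the 5 smallest adjusted p in each direction. From each list it names up to 4 called members, or else the 2 with the smallest p, and from each marker list also the 2 most abundant; predicted genes and clones are counted but not named. Some genes that the rule names are not reported here; they stayed in every fit, count and list. The 26 lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted together; an estimated correlation and fry served as alternatives. Shares of summed counts were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3 libraries. The fixed denominator was the library total. Because the ribosomal RNA row moves it, the report gives shares of counts outside that row, a choice made after seeing the data. Only that row was left out, and whether other rows also hold ribosomal RNA reads was not checked.

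Alternatives were RLE, upper-quartile and library-total scaling, no low-count filter and a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersion, the replicate number as a block, each library left out in turn, adjusted p under 0.1 and a 2-fold minimum. After seeing the data, 2 fits were added, without the ribosomal RNA row and with dKO replicate 3 thinned to the mean depth of the others. The labels give the same replicate numbers in both groups and no pairing. The steps were tested on simulated data for this comparison with 8444 genes, 200 of them changed: 146 genes were called, 6 of them falsely, and 41.8% of 1.5-fold, 77.6% of 2-fold and 90.9% of 4-fold changes were recovered. Genes were drawn independently, and apart from the changed genes all simulated libraries had the same make-up, the ribosomal RNA row included. The simulation therefore did not test the scaling for the low ribosomal RNA share of dKO replicate 3. Figures were drawn with matplotlib 3.10.9.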

Results

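Retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve, were, per the labels, sorted from mouse retinas, and total RNA of the sorted cells was sequenced. The mice carried floxed Myh9 and Myh10, and their eyes had received the viral vector AAV2 with either GFP (labelled WT, 3 libraries) or Cre recombinase (labelled dKO, 3 libraries) 2 weeks earlier. Each library came from 3 retinas of 3 mice. Total counts were 5071878, 4730540 and 6146226 in WT replicates 1 to 3 and 5634316, 5146054 and 4569880 in dKO replicates 1 to 3. A single ribosomal RNA gene row, CT010467.1 on chromosome 17, took 90.2%, 92.7% and 92.8% of the WT libraries and 89.8%, 91.2% and 64.2% of the dKO libraries. All other genes together held 346037 to 576060 counts in 5 libraries and 1636581 in dKO replicate 3, which was 3.53 times the mean of the other 5. The first principal component, with 31.0% of the variance, placed the 3 WT libraries below 0 and the 3 dKO libraries above it. Library pairs within a group differed by more than counting noise over protein-coding genes (chi-square per degree of freedom 1.12 to 1.48). Whether preparations of 1 pool would also give this was not tested. Each library was counted as 1 replicate. The labels describe triplicate pools of 3 retinas from different mice. They do not say whether the replicates of a group share mice, so p-values measure the spread between these libraries, which may be technical.

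**Figure D1:**
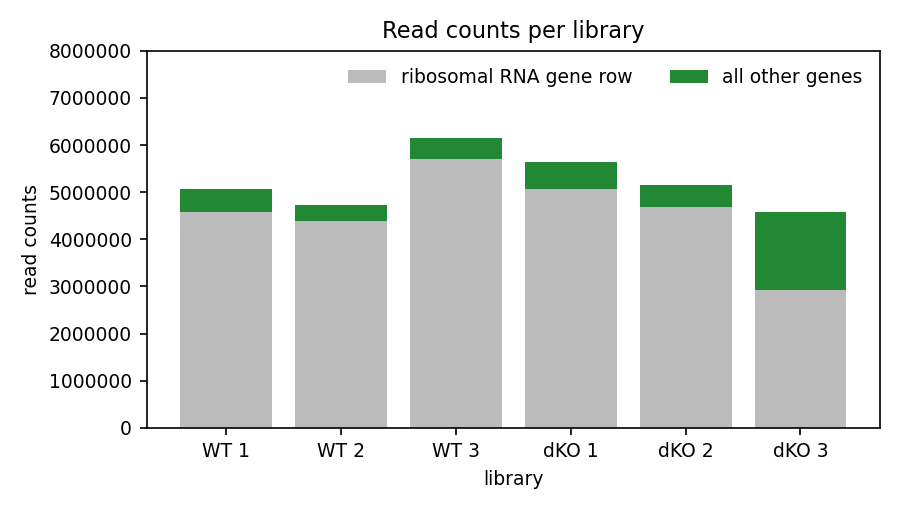
Read counts per library (vertical axis) for the 3 WT and 3 dKO libraries (horizontal axis), with the ribosomal RNA gene row in grey and all other genes stacked above it in green. The grey part takes 89.8% to 92.8% of 5 libraries and 64.2% of dKO replicate 3.

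The comparison was set up to ask how sorted RGCs differ after Cre delivery meant to delete Myh9 and Myh10, which encode the heavy chains of nonmuscle myosin IIA and IIB, the motor proteins that contract actin filaments. Myh9 (ENSMUSG00000022443, chromosome 15, 77760587 to 77842175 in GRCm38) was at 64.2 ± 3.91 CPM (counts scaled to a common library size; SD, n = 3) in the libraries labelled WT and 62.7 ± 4.13 (SD, n = 3) in those labelled dKO. Myh10 (ENSMUSG00000020900, chromosome 11, 68691559 to 68816632) was at 18.72 ± 2.08 and 18.00 ± 3.39 CPM (SD, n = 3 each). The log2 fold change was -0.044 ± 0.098 (SE) for Myh9 and -0.15 ± 0.14 for Myh10, with edgeR adjusted p of 0.908 and 0.735. The 95% intervals allow a fall of at most 15.3% for Myh9 and 25.7% for Myh10. Myh14, the heavy chain of nonmuscle myosin IIC, was at 13.7 ± 1.46 and 16.1 ± 2.46 CPM (SD, n = 3 each; log2 fold change 0.17 ± 0.15, adjusted p = 0.720). Neither targeted gene was therefore detectably lower in the libraries labelled dKO. Counts cover the whole gene, exons outside the floxed part included, so they do not check the deletion itself.

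**Figure D2:**
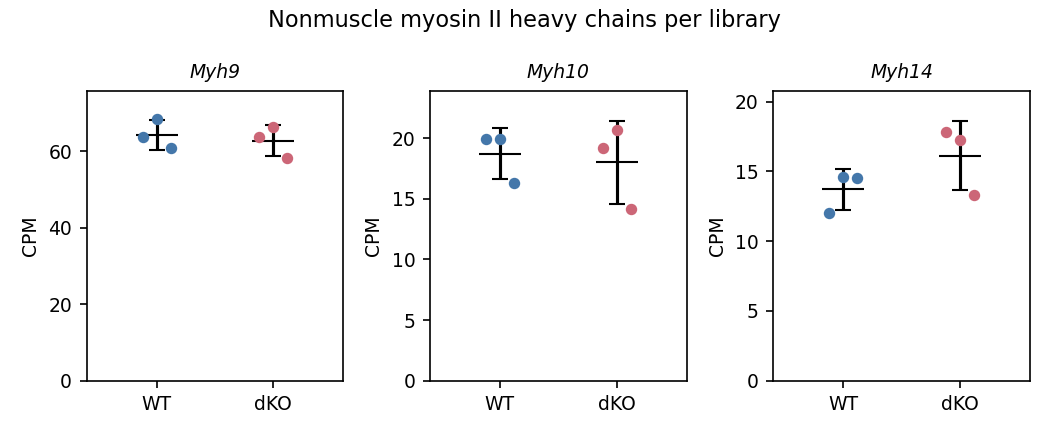
CPM (vertical axis, from 0) of Myh9, Myh10 and Myh14 in the libraries labelled WT (blue) and dKO (red); points are single libraries, horizontal bars are means and error bars are SD (n = 3). Myh9 averaged 64.2 CPM in WT and 62.7 CPM in dKO.

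Of 8444 genes tested, 62 were higher and 100 lower in the libraries labelled dKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Prph2, a structural protein of the rod outer segment disc, rose from 16.03 ± 0.703 to 34.9 ± 3.25 CPM (SD, n = 3 each; adjusted p = 4.88e-10). Among the genes that fell, Rnf213, an interferon-inducible ubiquitin ligase, had the smallest adjusted p (4.88e-10), going from 92.8 ± 3.21 to 51.7 ± 0.886 CPM. Changes of more than 2-fold were found for 21 higher and 32 lower genes. The 3 WT and 3 dKO values did not overlap for 153 of the 162 called genes, and for 17.0% of all genes tested, where chance gives 10%. DESeq2 called 26 higher and 26 lower genes. Without WT replicate 1 the counts were 29 higher and 61 lower, and without dKO replicate 3, the library with the low ribosomal RNA share, they were 50 higher and 66 lower.

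Rod photoreceptor transcripts rose together, while bipolar cell transcripts fell. Of 14 rod markers tested, 8 rose and none fell over all genes (13 rose adjusted over the list alone), with a median log2 fold change of 0.95. These included Prph2 (log2 fold change 1.11 ± 0.12, SE), Gnat1, the rod transducin alpha subunit (0.96 ± 0.12), and Sag, rod arrestin (0.87 ± 0.12). Of 11 bipolar markers, 4 fell and none rose (5 fell adjusted over the list alone), with a median of -0.32. Prkca, a protein kinase of rod bipolar cells, fell from 28.0 ± 3.21 to 15.7 ± 0.845 CPM (SD, n = 3 each). Trpm1, the transduction channel of ON bipolar cells, changed by -0.57 ± 0.10 (SE), and Gpr179 and Grm6, which act upstream of that channel, by -0.66 ± 0.12 and -0.67 ± 0.19. Camera's adjusted p was 9.56e-37 for the rod list and 1.16e-06 for the bipolar list (0.0296 and 0.0351 with an estimated correlation). Of 3 tested members of the cone list, Gnat2, the cone transducin alpha subunit, fell (-1.41 ± 0.34). Gnb3 (-0.36 ± 0.13) and Gngt2 (-0.30 ± 0.31) did not pass, and 2 members fell adjusted over the list alone. Gnb3 sets the list median and stood at 22.0 CPM in WT against 4.41 for Gnat2. Whether the Gnb3 reads came from cones or from other cells was not tested. Camera's adjusted p for the list was 0.00410, and 0.163 with an estimated correlation. Slc6a9, a glycine transporter and the only amacrine marker tested, rose (1.96 ± 0.38; 1 adjusted over the list alone), but not with limma-voom (adjusted p = 0.0641). Slc6a9 had only 5, 3 and 6 counts in WT replicates 1 to 3, so the size of its change is uncertain. DESeq2 did not call Grm6 (adjusted p = 0.483) and Gnat2 (0.172). The call of Grm6 was lost without any 1 library except dKO replicate 2 (adjusted p 0.0567 to 0.159), that of Gnat2 without WT replicate 1 (0.0552) or dKO replicate 3 (0.148), and that of the cone list without dKO replicate 3 (0.134). The cone median of -0.36 became -0.64 over 5 members without WT replicate 1 and -0.21 over 4 members without dKO replicate 3 (-0.42 and -0.25 over the same 3). As shares of counts outside the ribosomal RNA row, rod markers took 0.194% ± 0.0127 in WT and 0.392% ± 0.0410 in dKO, and bipolar markers 0.176% ± 0.00467 and 0.131% ± 0.00346 (SD, n = 3 each; two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 allow).

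**Figure D3:**
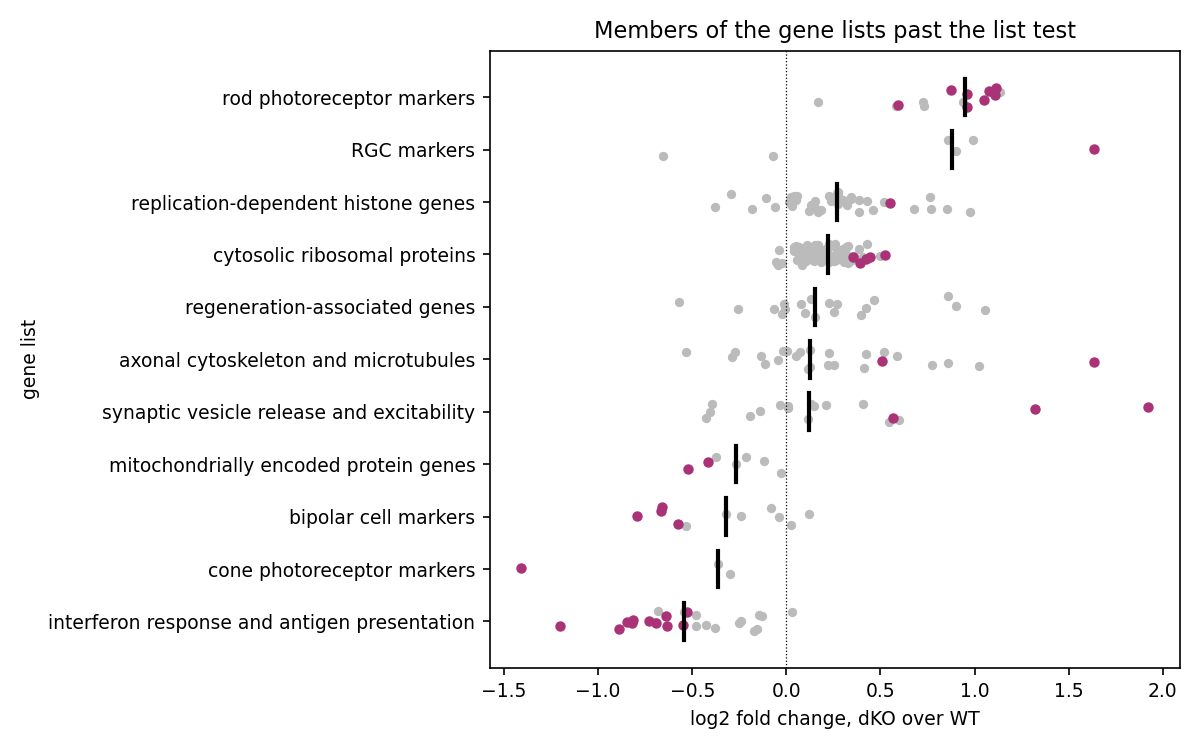
Log2 fold change of dKO over WT (horizontal axis) for each tested member of the 11 gene lists past the list test (vertical axis). Purple points passed adjusted p 0.05 over all genes, grey points did not, and black bars are list medians, from 0.95 for rod markers down to -0.54 for the interferon list; points are spread vertically only for visibility.

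Interferon-stimulated genes were lower in the libraries labelled dKO. Of 25 tested members of the interferon response and antigen presentation list, 11 fell and none rose (16 fell adjusted over the list alone), and 24 had a negative value, with a median log2 fold change of -0.54. Ifit1 fell from 8.85 ± 1.04 to 3.42 ± 1.14 CPM and Ifit3 from 20.996 ± 1.34 to 11.9 ± 0.220 CPM (SD, n = 3 each). Both encode antiviral proteins. Stat2 (-0.84 ± 0.17, SE), a transcription factor of the interferon pathway, also fell. Outside the list, the interferon-inducible genes Slfn8 (-1.61 ± 0.35), Oas3 (-1.82 ± 0.43) and Ifi207 (-1.52 ± 0.40) fell, as did Ms4a4c (-1.52 ± 0.43). Camera's adjusted p for the list was 2.77e-22, and 0.00965 with an estimated correlation. DESeq2 did not call Slfn8 and Oas3 (adjusted p = 0.0690 each), Ifi207 (0.156) and Ms4a4c (0.262). Leaving out single libraries ended the calls of Slfn8 (0.161 without WT replicate 1), Oas3 (0.0665 without WT replicate 1 and 0.127 without WT replicate 2), Ifi207 (0.0556 to 0.172 without any library except dKO replicate 3, without which its log2 fold change was -2.11) and Ms4a4c (0.0665 to 0.270 without any of the 6).

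Antibody genes made up the most strongly changed transcripts in both directions. Ighv5-4, Ighv9-3 (log2 fold change 4.01 ± 0.39, SE), Igkv4-63 (3.49 ± 0.52) and Igkv6-15 (2.80 ± 0.36), which encode variable segments of antibody chains, were higher in the libraries labelled dKO. Ighv5-4 had 1 count in WT and 140 in dKO, a scaled ratio of 66.2 (95% exact binomial interval 11.7 to 2633, counting error only). The few WT counts leave the size of these changes uncertain: without 1 library the log2 fold change was 5.08 for Ighv9-3 (WT replicate 2), 4.78 for Igkv4-63 (WT replicate 3) and 3.51 for Igkv6-15 (WT replicate 1). Igkv6-14 (-2.23 ± 0.39), Ighv7-3 (-2.22 ± 0.48), Igkv12-46 (-1.95 ± 0.36), Igkv11-125 (-1.54 ± 0.44), Ighv1-42 (-1.42 ± 0.18) and Ighv1-9 (-1.33 ± 0.17) were lower. So were the constant regions Iglc1 (-2.21 ± 0.28) and Ighg2b, which went from 139 ± 35.1 to 75.2 ± 4.99 CPM (SD, n = 3 each). In all, 23 of 36 tested immunoglobulin genes were called, 5 higher and 18 lower, against 139 of the 8408 other genes. A two-sided Fisher's exact test gave an odds ratio of 105 (p = 1.21e-31). The group was chosen after its values were seen, and the test takes genes as independent, so its p is only descriptive. Variable segments are near-identical copies that can share reads, so single segments are uncertain. Without dKO replicate 3 the log2 fold change of Iglc1 was -1.52. DESeq2 did not call Iglc1 (adjusted p = 0.0938) and Igkv11-125 (0.277), and calls were lost for Ighv7-3 without WT replicate 1 (0.157) or WT replicate 3 (0.0712) and for Igkv11-125 without any library except WT replicate 3 (0.0887 to 0.362).

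Neuronal transcripts were sparse, and a few were higher in the libraries labelled dKO. The RGC marker list took 0.0317% ± 0.00331 of counts outside the ribosomal RNA row in WT and 0.0441% ± 0.00220 in dKO (SD, n = 3 each), and only 6 of its 22 members in the table were abundant enough to test. Nefl, the light neurofilament chain, rose from 2.24 ± 0.718 to 7.16 ± 0.583 CPM, while Thy1 (-0.073 ± 0.168, SE) and Isl1 (-0.65 ± 0.23) did not pass. Whether the Thy1 and Isl1 reads came from RGCs or from other cells was not tested. Of 6 tested RGC subtype markers only Spp1 (osteopontin), a marker of alpha RGCs that macrophages also express, rose (1.52 ± 0.28), and the macrophage gene Lyz2 rose as well (0.50 ± 0.10); Jam2 (-0.43 ± 0.17) and Kcng4 (-0.15 ± 0.18) did not. In the axonal cytoskeleton list 2 of 26 tested members rose, Nefl and Map1b (0.51 ± 0.12), and in the synaptic and excitability list 3 of 18 rose, among them Cplx2 (1.32 ± 0.30), a regulator of vesicle release, and the sodium channel gene Scn1a (1.92 ± 0.44). None of 19 regeneration-associated genes passed over all genes (2 higher adjusted over the list alone); the smallest p belonged to the growth cone gene Gap43 (0.90 ± 0.30, adjusted p = 0.1203) and Gadd45a (1.05 ± 0.37, 0.138). The long noncoding RNA Snhg11 rose by 1.63 ± 0.35. In WT replicates 1 to 3, Scn1a had only 4, 3 and 3 counts and Snhg11 10, 3 and 4. The size of their changes is therefore uncertain. Adjusted over the list alone, 4 members rose and 1 fell among RGC markers, 1 rose and 1 fell among RGC subtype markers, 4 rose among axonal cytoskeleton genes and 4 rose among synaptic genes.

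By camera, the RGC (median log2 fold change 0.88, adjusted p = 0.00613), axonal cytoskeleton (0.13, 0.00198), synaptic (0.12, 0.0198) and regeneration (0.15, 0.0244) lists were higher in the libraries labelled dKO. With an estimated correlation their adjusted p was 0.209, 0.0934, 0.242 and 0.209, so none of these list calls held there. With fry it was 0.112, 0.0117, 0.0965 and 0.0872, so only the axonal cytoskeleton call held. Leaving out 1 library also changes which members pass the filter. Over the same members, the RGC median was 0.48 without WT replicate 1 and the regeneration median 0.24 without WT replicate 2. With newly tested members, the RGC median was 0.51 without WT replicate 2 (1.01 over the same 6), and the synaptic median 0.24 without WT replicate 2 and 0.27 without WT replicate 3 (0.13 and 0.10 over the same 18). The RGC list shares 6 of its members with the axonal and regeneration lists. Its call was also lost without WT replicate 1 (0.152), and the regeneration call without dKO replicate 3 (0.134). Among the genes, DESeq2 did not call Snhg11 (0.0824), Scn1a (0.111), Cplx2 (0.168) and Map1b (0.193). Calls were lost without WT replicate 1 for Scn1a (0.0519), Cplx2 (0.0894) and Map1b (0.186), and without dKO replicate 3 for Cplx2 (0.0646) and Map1b (0.112).

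**Figure D4:**
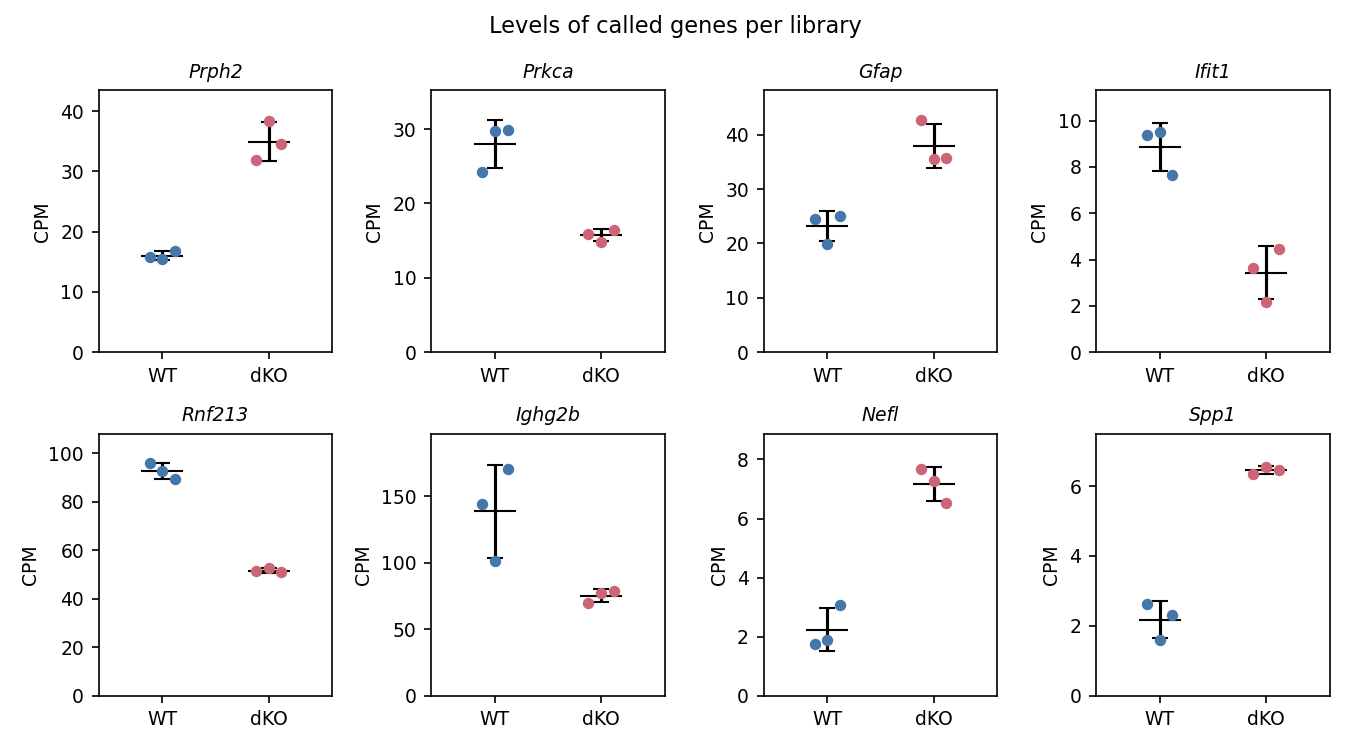
CPM (vertical axis, from 0) of 8 called genes in the libraries labelled WT (blue) and dKO (red); points are single libraries, horizontal bars are means and error bars are SD (n = 3). Prph2 averaged 16.03 CPM in WT and 34.9 CPM in dKO, and Rnf213 92.8 and 51.7 CPM.

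Glial transcripts were the most abundant of the cell type marker lists. Müller glia and astrocyte markers took 3.23% ± 0.0562 of counts outside the ribosomal RNA row in WT and 3.45% ± 0.145 in dKO (SD, n = 3 each; two-sided exact permutation p = 0.1), led by Glul, glutamine synthetase, at 1116 and 1159 CPM, and by Clu, at 641 and 729 CPM; neither passed, but Clu did with limma-voom (adjusted p = 0.00425, and 0.00544 with quality weights). Gfap, the intermediate filament of reactive glia, rose from 23.1 ± 2.77 to 37.9 ± 4.08 CPM and was the only called gene of 15 tested. Microglia and macrophage markers took 0.974% ± 0.0346 and 1.03% ± 0.0290, and of 19 tested only Lyz2, lysozyme, rose (0.50 ± 0.10, SE); Ctss (-0.10 ± 0.10) did not pass. Among 10 T and NK cell markers, Gzma, a granzyme, fell (-1.01 ± 0.28), while Lck (0.38 ± 0.19) and Cd3g (0.078 ± 0.222) did not pass. None of 8 endothelial and mural markers was called, among them Flt1 (-0.11 ± 0.10), Kdr (-0.089 ± 0.097) and Rgs5 (0.085 ± 0.095). Camera's adjusted p was 0.346 for Müller glia, 0.459 for microglia, 0.989 for T and NK cells and 0.965 for endothelial cells. Of the smaller lists, the oligodendrocyte genes Cnp (0.35 ± 0.13) and Mbp (0.33 ± 0.26) and the crystallin Cryab (0.11 ± 0.18) did not pass, and no pigment epithelium or red blood cell marker was abundant enough to test. Adjusted over the list alone, 1 Müller glia marker rose and 1 fell, 2 microglia markers and 1 oligodendrocyte gene rose, 1 T and NK cell marker fell, and no endothelial marker or crystallin passed. DESeq2 (0.401) and the replicate block (0.0651) did not call Gzma, and its call was lost without WT replicate 1 (0.177), WT replicate 2 (0.139), dKO replicate 2 (0.1002) or dKO replicate 3 (0.168).

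Cytosolic ribosomal protein genes were slightly higher in the libraries labelled dKO. Of 80 tested, 5 rose and none fell (31 rose adjusted over the list alone), 76 had a positive value and the median log2 fold change was 0.22, against 0.073 (central 95% 0.0020 to 0.14) for 10000 random lists matched on GC content and transcript length; examples are Rps28 (0.52 ± 0.13, SE), Rps7 (0.45 ± 0.12) and Rpl26 (0.39 ± 0.10). Of 7 mitochondrially encoded protein genes tested, mt-Nd4 (-0.52 ± 0.11) and mt-Nd5 (-0.42 ± 0.11) fell (3 fell adjusted over the list alone). The median of -0.27 became -0.53 without WT replicate 1, -0.11 without WT replicate 3, -0.47 without dKO replicate 1 and -0.16 without dKO replicate 3. Mitochondrially encoded genes took 5.17% ± 0.559 of counts outside the ribosomal RNA row in WT and 4.78% ± 0.425 in dKO (SD, n = 3 each), with overlapping values (two-sided exact permutation p = 0.4). Of 40 replication-dependent histone genes, only Hist1h1d rose (0.55 ± 0.16; 1 adjusted over the list alone), with a median of 0.27. Camera's adjusted p was 1.05e-16, 0.000597 and 9.96e-05, and with an estimated correlation 0.0351, 0.390 and 0.209. All 3 are multicopy or pseudogene-rich families whose reads can be shared. DESeq2 did not call Rps28 (0.265), Rps7 (0.269), Rpl26 (0.181), mt-Nd4 (0.108), mt-Nd5 (0.187) and Hist1h1d (0.639, and 0.0567 with the replicate block). Single omissions ended the calls of Rps28 (0.132 without WT replicate 1, 0.103 without WT replicate 2, 0.0534 without dKO replicate 3), Rps7 (0.132 without WT replicate 1, 0.101 without WT replicate 3, 0.185 without dKO replicate 3) and Rpl26 (0.0597 to 0.143 without any library except dKO replicate 1). The same held for mt-Nd4 (0.0744 without WT replicate 3, 0.195 without dKO replicate 3), mt-Nd5 (0.182 without WT replicate 2, 0.0862 without WT replicate 3, 0.233 without dKO replicate 3), the mitochondrial list (0.118 without WT replicate 3) and Hist1h1d (0.339 without WT replicate 1, 0.142 without WT replicate 3, 0.0581 without dKO replicate 2, 0.315 without dKO replicate 3).

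No actomyosin gene and no receptor for a repulsive or inhibitory cue passed over all genes. Of 38 actomyosin genes the smallest p belonged to the tropomyosins Tpm1 (0.58 ± 0.17, SE; adjusted p = 0.0629) and Tpm2 (1.01 ± 0.44; 0.286), and the list's camera adjusted p was 0.759. Among 24 receptors for repulsive and inhibitory cues, Epha7 stood just outside the threshold (-0.60 ± 0.18; 0.0507), Pirb was at 0.84 ± 0.32, and the list's adjusted p was 0.213 (1 lower adjusted over the list alone). Growth control regulators (24 tested, Akt2 0.42 ± 0.16, Rps6kb1 0.73 ± 0.30) had an adjusted p of 0.977, axon injury and stress genes (16, Slc7a11 0.91 ± 0.40, Map3k13 -0.86 ± 0.39) 0.977, p53 targets (13, Mdm2 -0.43 ± 0.23, Ei24 0.27 ± 0.18) 0.619, and immediate-early and SRF targets (16, Dusp1 0.63 ± 0.23, Acta2 0.41 ± 0.16) 0.808. Cholesterol synthesis genes (17, Sc5d 0.45 ± 0.20, Msmo1 0.45 ± 0.24) had 0.965, extracellular matrix and integrin genes (22, Col4a1 -0.32 ± 0.13, Sparc 0.25 ± 0.10) 0.989, mitosis genes (7, Mki67 -0.66 ± 0.23, Mcm6 0.48 ± 0.26; 1 lower adjusted over the list alone) 0.459, RGC subtype markers 0.989 and the 3 myosin heavy chains 0.989. Epha7 passed with RLE scaling (0.0491), the CPM filter (0.0435), robust dispersion (0.0474), the replicate block (0.0238) and without dKO replicate 3 (0.0368), Tpm1 with upper-quartile scaling (0.0442), and Sparc with limma-voom (0.0279, and 0.0223 with quality weights). No member of the actomyosin, growth control, axon injury, p53, immediate-early, cholesterol, matrix and myosin heavy chain lists passed adjusted over the list alone. Median and mean differ in sign for the growth control, immediate-early, cholesterol, RGC subtype and T and NK cell lists, and median and camera direction for the myosin and axon injury lists as well.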

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

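Fits without the ribosomal RNA row, with dKO replicate 3 thinned and with shares outside that row were chosen after seeing the data. The 62 higher and 100 lower genes became 26 and 26 with DESeq2 (the cause was not tested), 108 higher at adjusted p under 0.1, and 21 and 32 with a 2-fold minimum, these cutoffs being looser or stricter by construction. With library totals as the only scaling, 3 were higher and 0 lower (100% higher against 38.3%). The median of all genes then shifted by 1.21 on the log2 scale, and standard errors grew. Gnat1, for example, went from 0.96 ± 0.12 to 2.16 ± 0.85 (SE) and lost its call (edgeR adjusted p = 0.301). Left out by this scaling is the TMM factor of 3.43 for dKO replicate 3, the library with 64.2% ribosomal RNA. Leaving out single libraries gave 29 to 71 higher and 61 to 115 lower genes, the lowest without WT replicate 1. Other fits stayed within 1.5 times. Without the ribosomal RNA row 71 and 103 genes were called, 159 of the 162 among them, and with dKO replicate 3 thinned 62 and 73, with 121 of the 162. Thinning ended 3 of the 38 named calls still tested: Gzma (adjusted p = 0.188), Hist1h1d (0.0966) and mt-Nd5 (0.0956).

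Myh9, Myh10 and Myh14 passed the threshold in none of the fits run. Of 44 named calls, 44 stayed with RLE, with upper-quartile scaling and with the CPM filter, 41 without a filter and with limma-voom, 40 with quality weights, 42 with robust dispersion and 25 with DESeq2; in 26, no single omitted library ended the call. Calls lost without a filter, with limma-voom, with quality weights or with robust dispersion were those of Grm6, Gzma, Hist1h1d, Igkv11-125, Ms4a4c, mt-Nd5 and Slc6a9 (adjusted p 0.0524 to 0.0829). With library totals only, 3 kept the call and 12 turned sign: Gpr179 0.51, Grm6 0.55, Gzma 0.17, Ifit1 0.035, Ifit3 0.40, Ighg2b 0.37, mt-Nd4 0.64, mt-Nd5 0.77, Prkca 0.44, Rnf213 0.36, Stat2 0.38 and Trpm1 0.62. After subtracting the 1.21 shift, all 44 had their reported sign.

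The 7 higher and 4 lower lists became 2 and 2 with an estimated correlation and 3 and 2 with fry. As shares of the library total, dKO minus WT was 0.00147 percentage points for cone and 0.00977 for bipolar markers, -0.00026 and -0.0017 without dKO replicate 3 (highest without another library 0.00249 and 0.0158). Outside the ribosomal RNA row, differences turned sign for cone (-0.00991), bipolar (-0.0441), RGC subtype (-0.00295), endothelial (-0.00682) and mitochondrial genes (-0.386); the denominator is the cause by construction.

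With the replicate block 58 genes were higher and 100 lower, 148 of the 162 among them, and no list call changed. The block kept 42 of the 44 named calls, ending those of Gzma (adjusted p = 0.0651) and Hist1h1d (0.0567), and Epha7 passed (0.0238). Deviations of same-numbered libraries from their group means correlated at 0.026, 0.013 and 0.029 across genes, and each library correlated best with its own number. Some matching must come out best, so correlations this small do not decide on pairing. The numbers were not taken as pairing. With 346037 to 576060 counts outside the ribosomal RNA row in 5 libraries, small changes are easily missed. In the simulated data 41.8% of 1.5-fold changes were recovered, and smaller ones were not simulated.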

Other observations

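The tests on the myosin level, on antibody segments, on Y-linked and Xist counts and on the share of the main cell type, and the omission of single rod markers, were chosen only after the results were seen, as were the genes named in the next paragraph.

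Trim30a (log2 fold change -1.21 ± 0.16, SE, edgeR adjusted p = 5.03e-08), Igtp (-0.94 ± 0.14), Iigp1 (-1.04 ± 0.18) and Gbp9 (-0.97 ± 0.17), interferon-inducible genes outside the fixed list, were lower in the libraries labelled dKO; the last 3 encode GTPases of intracellular defence. Abca4 (0.85 ± 0.15), a retinoid transporter of photoreceptors, and Rbp3 (0.58 ± 0.11), the retinoid-binding protein of the interphotoreceptor matrix, were higher; neither is in the rod list. Ncam1, a neural adhesion molecule, fell by 0.57 on the log2 scale (SE 0.10) and Xist, the RNA that silences an X chromosome, from 123 to 81.7 CPM. As shares of counts outside the ribosomal RNA row, Xist did not overlap between the groups, but Y-linked counts did. The labels do not give the sex of the mice, and whether the sex mix differed between the groups was not tested. A difference in sex therefore cannot be separated from the group in any comparison here. The 8 genes named so far in this paragraph were among 19 called genes looked at. Of the 19, 15 kept the call whichever single library was left out, these 8 included. The other 4 were Ctsd (0.41 ± 0.10), Gpnmb (0.93 ± 0.25) and Fcgr3 (0.44 ± 0.12), which macrophages express, and the noncoding RNA Meg3 (1.17 ± 0.26), all higher. Their calls were lost without WT replicate 1 (adjusted p = 0.0942, 0.248, 0.238 and 0.121), for the first 3 also without WT replicate 2, for Gpnmb and Fcgr3 also without dKO replicate 1 or 2, for Fcgr3 also without dKO replicate 3 and for Meg3 also without WT replicate 3. DESeq2 did not call Gpnmb (0.381), Fcgr3 (0.438) and Meg3 (0.0713). Among the 15 that kept the edgeR call, it did not call Gm42418 (0.998), Lars2 (0.998), Igha (0.550) and Irf7 (0.0503), all lower in the libraries labelled dKO. Gm42418 went from 3175 to 1409 CPM and Lars2 from 525 to 239. Whether either row holds ribosomal RNA reads was not checked, so their fall may not be one of gene expression.

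Across the 10 splits of the 6 libraries into 3 and 3, the labelled split called 162 genes and 11 lists; 1 split reached each of these numbers, the labelled one. The highest count among the other splits was 1 gene and 5 lists. With 10 splits a share under 0.05 is out of reach.

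Myh9 and Myh10 were not detectably lower in the libraries labelled dKO. A candidate explanation is that the libraries hold little RNA from RGCs, the cells named on the labels: summed Müller glia and astrocyte markers exceeded summed RGC markers by at least 77.3 times in every library (77.3 to 117), and Glul alone stood at 1116 CPM against 10.7 for Thy1 in WT, although FACS was meant to remove glia. Exons outside the floxed part could also hold up the count; the lower 95% bound for Myh9 is -0.239 on the log2 scale, but without counts per exon this cannot be told apart from an uncut gene. Whether Cre acted in these cells stays untested.

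Antibody segments were shared among the libraries of a group and differed between groups. Of 76 variable segments with at least 20 counts, 8 were present in every library of 1 group and absent from the other, against at most 1 in any other split; Ighv2-9-1 had 29, 9 and 24 counts in WT and 0 in each dKO library, and Igkv4-86 had 0 in WT and 9, 13 and 40 in dKO. A possible explanation is that the libraries of a group were drawn from 1 pool of cells, but the chi-square per degree of freedom over segments, at most 4.36 within groups and on average 11.1 between groups, restates the pattern and would also arise with separate mice. Y-linked genes took 49 of 499313, 14 of 346037 and 31 of 441118 counts outside the ribosomal RNA row in the WT libraries. The chi-square p was 0.0092, under the 0.025 that a pool was to stay above and over the 0.001 set for excluding it. For dKO the chi-square p was 0.727. Xist shares differed within WT (chi-square p = 4.85e-05) and dKO (p = 3.27e-05). These tests cover counting error only, and whether uneven preparations of 1 pool would give such values was not tested. A pool therefore cannot be told apart from separate mice that shared antibody segments within a group for any other reason. Like antibody responses to GFP or Cre are only 1 possible reason, and the design leaves all of them untested.

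Rod markers were higher and bipolar markers lower in the libraries labelled dKO. A lower share of the main cell type would raise both. The bipolar median of -0.32 is part of the pattern itself, so it does not test this for the rod markers. Müller glia and astrocyte markers, the most abundant marker list, took 3.23% of counts outside the ribosomal RNA row in WT and 3.45% in dKO. No lower share was therefore seen for that list. GC content or transcript length is argued against. The central 95% of 10000 random lists matched on both ended at 0.19, below the rod median of 0.95. Of these 10000, 12 were as extreme as the bipolar list. More rod RNA of unchanged make-up, at a common 1.90-fold, stays open for the rod part: the rod markers varied beyond their errors (Cochran's Q, n = 14 genes taken as independent, p = 0.0376), but this rests on single genes, with p = 0.313 when Gngt1 (0.17 ± 0.25, SE) is left out. A change in sorting that favours rods over bipolar cells, and an effect of the vector or genotype on these cells, stay open as untested hypotheses.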
